A study of Mus musculus with 31 samples.

How the data were processed

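Total RNA of 31 samples was labelled with biotin and measured on 1 Affymetrix mouse expression array each, per the labels. The samples were NSC neurospheres from 3 brain regions (3 each), CSC lines from 8 Ptch heterozygous, p53 wild-type medulloblastomas with the 8 matched tumour tissues, and CSC from 2 medulloblastomas of mice heterozygous for Ptch and p53 (3 technical replicates each). The deposited values are log2 intensities per probe set, which the authors made with RMA (background correction, quantile normalization and median polish); its version, the probe set definition, any detection calls and a genome build are not given in the sources used here. The values, 0.417 to 12.9 on all 31 arrays, were used as deposited. Array medians lay between 3.166 and 3.324.

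Of 45101 probe sets, 34958 carried 1 gene symbol, 932 carried several and 9211 were not listed in the probe table; the last 2 kinds were left out. Symbols were checked through Entrez identifiers against a mouse gene table (34754 matched, 0 changed). Each gene was represented by its probe set with the highest mean over all arrays, chosen without regard to group, which gave 18194 genes, of which 9012 had more than 1 probe set. No gene was left out for low signal in the fits reported. The Y-linked genes Eif2s3y, Kdm5d and Uty in the samples with Eif2s3y under 2 were taken as a guide to the level of genes that are not expressed, a choice made after the data were seen. The 3 technical replicates of each p53 heterozygous tumour were averaged, which left 27 samples.

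Comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted over all genes by the Benjamini-Hochberg method, with a threshold of 0.05 and no minimum fold. All limma and camera tests were two-sided. The 9 NSC arrays shared 1 fit for the 3 regional comparisons (6 residual degrees of freedom). The 19 cultures shared another for the comparisons of tumour cultures (14 residual degrees of freedom), in which hindbrain NSC were the mean of the IV ventricle and cerebellar group means. A group of 2 tumours was thereby assumed to vary like the other cultures. Lines and tissues were compared with the tumour as a block (7 residual degrees of freedom), since both carry the same tumour identifier. The NSC share replicate numbers, but nothing says that a number marks an animal or a litter. The profiles of IV ventricle and SVZ and of cerebellar and SVZ cultures paired by number, those of IV ventricle and cerebellar cultures did not. With the replicate number as a block, 0, 196 and 280 genes were called in the IV ventricle against cerebellar, IV ventricle against SVZ and cerebellar against SVZ comparisons. Where nothing says that cultures come from separate animals, the p-values measure only the spread between these samples.

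Gene lists were tested with camera at a preset correlation of 0.01 and, as an alternative, with an estimated correlation, adjusted over the lists of 1 comparison. The 36 lists were written from textbook markers before the data were examined and cover regional patterning, signalling pathways, p53 targets, the cell cycle, brain and blood cell types, metabolism, imprinting and human medulloblastoma subgroup panels. Members were also counted as higher or lower, with p-values adjusted over all genes and over the list alone. A further 4 lists, of neural crest and Schwann cells, oligodendrocyte precursors, cartilage and melanocytes, were written after the data were seen. Only members not looked at before were tested in these.

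Genes were named by a rule also fixed before the data were examined. It takes Ptch1 and Trp53, and the 8 highest and 8 lowest log2 differences among called genes whose groups did not overlap, without predicted or clone symbols. It adds, for each list described, up to 4 members with the smallest p in the main direction and up to 2 in the other. A list could be described where camera called it, where at least 3 members were called or where the comparison concerned it. Only some of the genes so named are given.

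Distances were Euclidean over all genes from each line to each NSC group mean, and differences of distances were tested with an exact two-sided sign-flip test over the 8 lines. Shared calls were set beside independent lists and simulations of unchanged groups with shared controls. Chromosome shifts were medians over the brighter 9082 genes. Permutation splits of the samples numbered 10 for 3 against 3, and otherwise 100 including the real split. Component scores are from a principal component analysis of the 27 samples. Figures used Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.

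Alternatives fixed before the data were examined were 3 array scalings, leaving out dim genes, averaging or keeping all probe sets, a trended robust prior, a 2-fold minimum, other sets of arrays and reference groups, the replicate and tumour blocks, date marks of the CSC arrays and leaving out each culture. Those added later were date marks of the NSC arrays and of the tissue pairs as blocks, the date mark as a random block with the first array of each p53 heterozygous tumour, chromosomes without a shift in these tumours or in any tumour culture, the joint hindbrain set and an IV ventricle mean without replicate 2. What the date marks in the sample names stand for is not stated, and they are used only as groups of arrays. On simulated data with the same designs, 32.8% to 67.2% of genes changed 1.5-fold, 68.7% to 89.6% of those changed 2-fold and at least 95.5% of those changed 4-fold were recovered, with 5 to 10 false calls. A list with all members raised 2-fold was found in 7 of 7 designs, and 2 of 30 unchanged lists were called in 1 design. Genes were drawn independently in these simulations, so they do not test camera on lists whose members vary together.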

Results

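Gene expression was measured on 31 Affymetrix mouse arrays covering 27 biological samples. Neurospheres, free-floating cultures that enrich for neural stem cells (NSC), had been grown from the subventricular zone (SVZ) of the forebrain, from the region of the fourth (IV) ventricle of the hindbrain and from cerebellar white matter of mice at postnatal day 7. There were 3 cultures per region. Medulloblastoma is a tumour of the cerebellum, and mice that carry only 1 working copy of Ptch1, the receptor that restrains Sonic hedgehog (Shh) signalling, develop it. Stem-like tumour cultures (called CSC in the labels) came from 8 tumours of Ptch heterozygous mice with intact p53, and for each of these 8 lines the matched tumour tissue was also measured. A further 2 tumours, 27 and B, came from mice heterozygous for both Ptch and p53, with 3 technical replicate arrays each, which were averaged to 1 value per tumour. The values were RMA log2 intensities, array medians lay between 3.17 and 3.32, and 18194 genes were tested with 1 probe set each. On an array platform the number of arrays limits the precision. Below, differences are log2 differences ± SE of the limma fit, on which 1 unit is a 2-fold change, and a gene is called higher or lower at an adjusted p under 0.05. In 15 samples without Y signal the Y-linked genes read 0.7 to 1.6, a guide to the level of genes that are not expressed. Where the lower group mean lay there, the difference is given as at least the higher mean less 1.57, the highest of these readings, as for 17 of 255 called differences of genes followed by name. The guide rests on 3 genes, and other probe sets may read higher without expression. The sex-linked gene Xist read 3.1 to 4.0 in NSC replicate 2 of each region and in lines and tissues 92 and 68, all with Y signal. Differences with a lower group mean above 1.57 are given as measured and may also touch background.

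Principal component 1 held 57.4% of the variance and placed the 8 tumour tissues, at 86.7 to 94.0, apart from every culture, at -45.9 to -18.0. Component 2, with 12.3%, placed the 2 p53 heterozygous tumour cultures, at 91.8 and 91.7, apart from the 8 p53 wild-type lines, which lay between -7.44 and 7.96. The 9 NSC cultures lay together on both components, and the next comparison asked what still separated them by region.

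**Figure D1:**
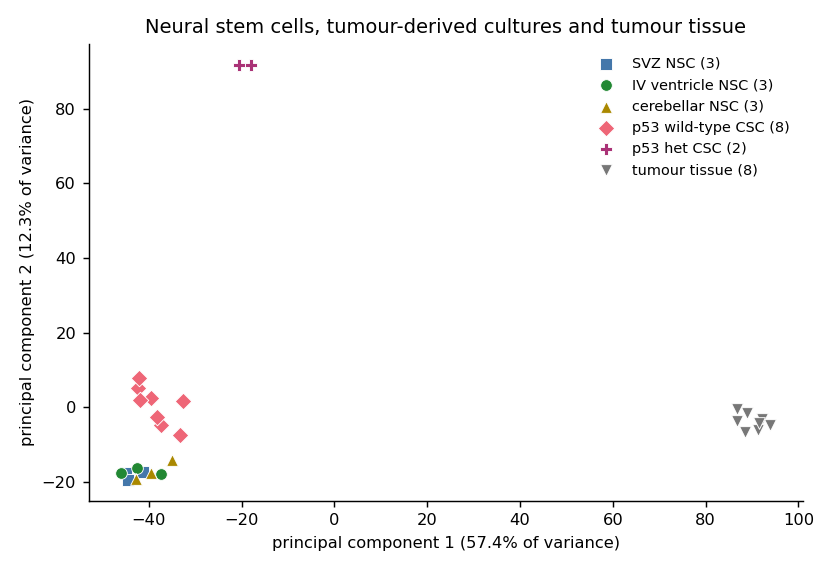
Scores of 27 samples on the first components of variation over 18194 genes; each point is 1 culture, tumour or tissue, the axes are in log2 units, and the percentages give the share of variance. The tissues lie at 86.7 to 94.0 on component 1 and the p53 heterozygous cultures at 91.8 and 91.7 on component 2.

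NSC from the hindbrain kept a regional code that set them apart from forebrain NSC grown in the same way. The forebrain homeobox genes Six3, Emx2 and Lhx2 were low in IV ventricle NSC and high in SVZ NSC. Emx2 read 2.02 ± 0.95 (SD, n = 3) against 6.02 ± 0.10 (SD, n = 3), a log2 difference of -4.00 ± 0.38 (adjusted p = 0.00173). Lhx2 differed by -3.88 ± 0.42 (adjusted p = 0.00354) and Six3 by -2.69 ± 0.26 (adjusted p = 0.00173). Six3os1, the transcript antisense to Six3, was lower by at least 3.87 (adjusted p = 6.54e-08). In the other direction, the Iroquois homeobox genes Irx2 (2.93 ± 0.32, adjusted p = 0.00354) and Irx3 (2.65 ± 0.25, adjusted p = 0.00173), which act in midbrain and hindbrain patterning, were higher in IV ventricle NSC.

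Beyond patterning genes, the largest rise in IV ventricle over SVZ NSC was that of Sparcl1, which encodes a secreted matrix glycoprotein of astrocytes, from 3.46 ± 0.51 (SD, n = 3) to 9.08 ± 0.66 (SD, n = 3), a difference of 5.62 ± 0.47 (adjusted p = 0.00114). Chl1, a neural cell adhesion molecule, rose by 2.80 ± 0.17 (adjusted p = 1.53e-04). Anxa3, an annexin, fell by 3.80 ± 0.46 (adjusted p = 0.00594), Fndc3c1 fell by 3.32 ± 0.19 (adjusted p = 1.28e-04), and Mfng, an enzyme that adds sugars to Notch receptors, fell by 1.62 ± 0.15 (adjusted p = 0.00169). In all, 139 of 18194 genes were called, 64 higher and 75 lower in IV ventricle NSC. Wls, which carries Wnt proteins to the cell surface (3.60 ± 0.57, adjusted p = 0.0214), Irx5 (2.53 ± 0.37, adjusted p = 0.0143), the hindbrain gene Gbx2 (1.59 ± 0.25, adjusted p = 0.0214) and Pax3 (2.19 ± 0.36, adjusted p = 0.0244) were also higher. The calls of these 4 genes did not hold with fewer cultures. All 4 were lost without SVZ replicate 1 or 2, Wls, Gbx2 and Pax3 without IV ventricle replicate 1, Gbx2 and Pax3 without SVZ replicate 3, and Wls without IV ventricle replicate 3. Their differences stayed in the same direction in all 6 leave-outs, at 3.04 to 4.38 for Wls, 2.18 to 2.93 for Irx5, 1.40 to 1.70 for Gbx2 and 1.79 to 2.47 for Pax3. Wls (adjusted p = 0.0503) and Pax3 (adjusted p = 0.0655) also lost their calls with only the arrays compared, and Wls with a trended robust prior (adjusted p = 0.067). Across every named gene that lost its call in a leave-out the adjusted p ranged from 0.052 to 0.2. The count of called genes fell to 51 without SVZ replicate 2, to 60 without SVZ replicate 1 and to 86 without IV ventricle replicate 1.

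Of 19 measured forebrain patterning genes, 0 were higher and 4 lower in IV ventricle than in SVZ NSC (0 and 5 adjusted over the list alone). The list was lower by camera (adjusted p = 8.85e-04; adjusted p = 0.121 with an estimated correlation). Of 18 midbrain-hindbrain patterning genes, 4 were higher and 0 lower (5 and 1 adjusted over the list alone). The list was higher (adjusted p = 8.85e-04; adjusted p = 0.121 with an estimated correlation). The Hox genes, which mark the hindbrain and spinal cord, had 1 member of 19 called, Hoxa4 (1.51 ± 0.28, adjusted p = 0.047), with 6 higher adjusted over the list alone. The list was higher as a whole (adjusted p = 0.00445; adjusted p = 0.453 with an estimated correlation). Hoxa4 lost its call in every leave-out but that of IV ventricle replicate 2 (adjusted p up to 0.2, with differences of 1.21 to 1.80 over the 6). It also lost it in every other setting that measured it except the date mark as a block (adjusted p from 0.0545 to 0.764). The Hox list lost its call without IV ventricle replicate 3 (adjusted p = 0.0802). Neural stem and radial glial markers were lower as a list, with 0 of 22 members called over all genes and 4 lower adjusted over the list alone (adjusted p = 5.60e-05; adjusted p = 0.301 with an estimated correlation). The member Nr2e1, a nuclear receptor that maintains forebrain stem cells, read 2.36 ± 2.02 (SD, n = 3) against 6.53 ± 0.39 (SD, n = 3; adjusted p = 0.0716). The p53 target (0 of 30 called), Notch (1 of 21 lower, Mfng) and hypoxia (0 of 19 called) lists were also lower, and the human SHH medulloblastoma panel (1 of 5 higher) was higher, with the same counts adjusted over the lists alone. Their adjusted p values were 0.00445, 0.0277, 0.0263 and 0.021, and adjusted p = 0.324, 0.453, 0.844 and 0.369 with an estimated correlation. All 4 lost their calls in 1 or more leave-outs. The hypoxia list did so without IV ventricle replicate 2 or 3 or SVZ replicate 1 or 3 (adjusted p 0.0742 to 0.173), and the SHH panel without IV ventricle replicate 1 or 3 or SVZ replicate 1 (adjusted p 0.0575 to 0.111). The Notch list did so without IV ventricle replicate 2 or SVZ replicate 3 (adjusted p = 0.104 and 0.0941), and the p53 list without IV ventricle replicate 2 (adjusted p = 0.0503). The sample names carry date marks, and replicate 3 of every region shares 1 mark. The larger mark common to all regions, called the shared mark below, holds only 1 IV ventricle array, 2 SVZ and 2 cerebellar arrays. Within it 58 genes were called, with the lone IV ventricle array assumed to vary like the others. There the calls of Sparcl1 (5.76, adjusted p = 0.0687), Lhx2 (-3.54, adjusted p = 0.0539), Gbx2 (1.94, adjusted p = 0.255), Pax3 (1.65, adjusted p = 0.0669), Hoxa4 (1.49, adjusted p = 0.171) and the midbrain-hindbrain (adjusted p = 0.0596), p53 target (adjusted p = 0.0596), Notch (adjusted p = 0.117) and hypoxia (adjusted p = 0.442) lists were lost, in an arm too small to tell date from sampling. With the date mark as a block 193 genes were called and these 5 genes kept their calls, but the Notch (adjusted p = 0.151) and hypoxia (adjusted p = 0.12) lists lost theirs. The Notch list also lost its call with the replicate number as a block (adjusted p = 0.094).

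Cerebellar NSC also differed from SVZ NSC in regional genes. Sparcl1 was higher by 5.79 ± 0.47 (adjusted p = 0.00106), Irx2 by 2.71 ± 0.32 (adjusted p = 0.00443) and Irx3 by 2.59 ± 0.25 (adjusted p = 0.00183). Emx2 (-4.34 ± 0.38, adjusted p = 0.0013), Lhx2 (-3.95 ± 0.42, adjusted p = 0.00343) and Six3 (-2.86 ± 0.26, adjusted p = 0.0013) were lower. Rnf43, a ubiquitin ligase that removes Wnt receptors from the cell surface, read 5.21 ± 0.40 (SD, n = 3) in cerebellar and 2.12 ± 0.24 (SD, n = 3) in SVZ NSC, a difference of 3.08 ± 0.29 (adjusted p = 0.00178). Of 18194 genes, 201 were called, 104 higher and 97 lower in cerebellar NSC. The calls in the 2 hindbrain comparisons shared 116 genes in the same direction, 55 higher and 61 lower, with 0 in opposite directions. Independent lists of these lengths would share 1.54, but both comparisons use the same SVZ cultures, which alone raises the overlap. Unchanged groups simulated against shared SVZ cultures shared 0 called genes over 50 draws. Such groups yield hardly any calls, so that 0 does not show how far the shared cultures raise the overlap. Across all genes the log2 differences correlated at r = 0.879, against a mean of 0.501 in that simulation, with a covariance of 0.0912 against 0.0186.

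The forebrain patterning list was lower in cerebellar NSC, with 0 of 19 members higher and 4 lower (1 and 6 adjusted over the list alone; adjusted p = 0.00539, and adjusted p = 0.229 with an estimated correlation). The midbrain-hindbrain list was higher, with 4 of 18 members higher and 0 lower (7 and 1 adjusted over the list alone; adjusted p = 0.00343, and adjusted p = 0.229 with an estimated correlation). Neural stem and radial glial markers were again lower, with 1 of 22 called, Id4, an inhibitor of neurogenic transcription factors (-0.63 ± 0.12, adjusted p = 0.035). Camera gave an adjusted p of 2.05e-04, and adjusted p = 0.373 with an estimated correlation. Cholesterol synthesis genes were lower as a list with 0 of 16 called, 0 also adjusted over the list alone (adjusted p = 0.00343, and adjusted p = 0.683 with an estimated correlation; adjusted p = 0.118 within the shared date mark). Id4 lost its call in each of the 6 leave-outs, at differences of -0.70 to -0.53 (adjusted p between 0.0501 and 0.149 over the named genes lost). The count fell to 61 without SVZ replicate 1, to 66 without SVZ replicate 2, to 81 without cerebellar replicate 3, to 98 without cerebellar replicate 1 and to 128 without SVZ replicate 3. It was 144 within the shared date mark and 728 with the date mark as a block.

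**Figure D2:**
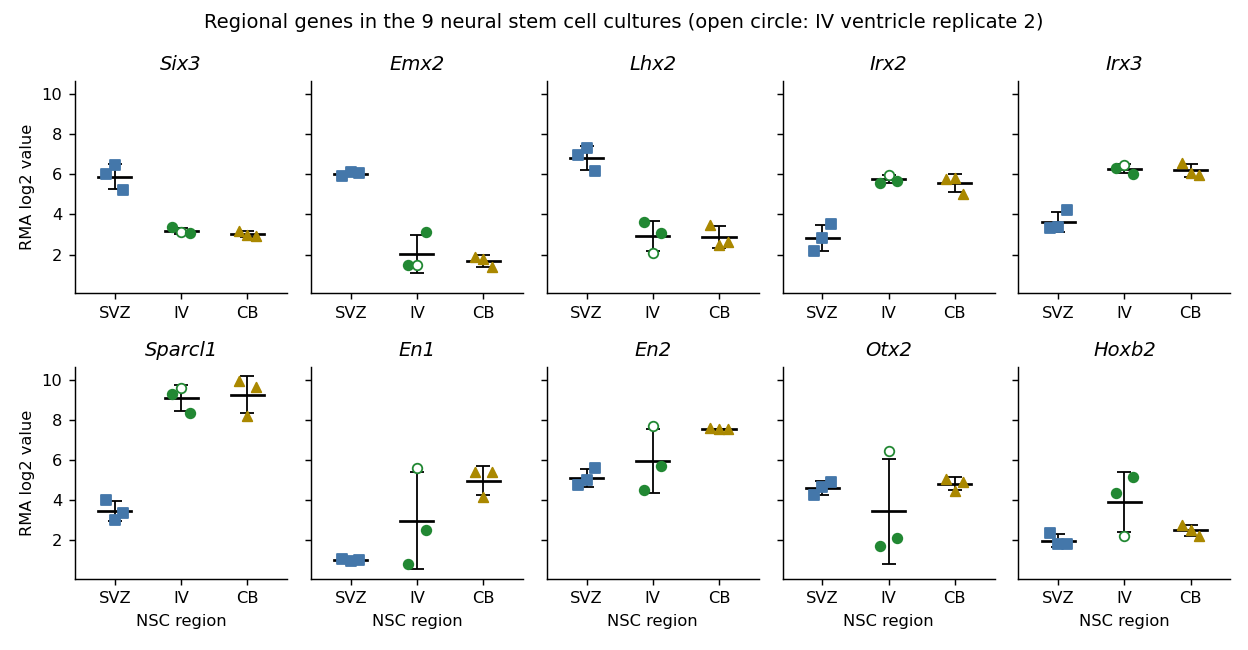
RMA log2 values of 10 regional genes in the 9 NSC cultures; each symbol is 1 culture, the bar is the mean of 3 and the whiskers are ± 1 SD. Six3, Emx2 and Lhx2 are higher in SVZ cultures and Irx2, Irx3 and Sparcl1 in hindbrain cultures, while IV ventricle replicate 2 (open circle) reads 7.67 for En2 and 6.44 for Otx2 against 4.50 and 1.72 in replicate 1.

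Between the 2 hindbrain populations, IV ventricle and cerebellar NSC, limma called 0 of 18194 genes, with 559 at an unadjusted p under 0.05. In patterning genes IV ventricle replicate 2 read like a cerebellar culture. En2, an engrailed gene of the midbrain-hindbrain boundary, was 7.57, 7.52 and 7.53 in the cerebellar cultures and 4.50, 7.67 and 5.72 in IV ventricle replicates 1, 2 and 3. Otx2 was 5.07, 4.46 and 4.92 in cerebellar and 1.72, 6.44 and 2.13 in IV ventricle cultures. Hoxb2, a hindbrain Hox gene, was 2.78, 2.50 and 2.22 in cerebellar and 4.35, 2.22 and 5.13 in IV ventricle cultures. Without IV ventricle replicate 2, 7 genes were called: Otx2 (-2.89 ± 0.24, adjusted p = 0.0078), Efna5, an ephrin ligand (-5.02 ± 0.43, adjusted p = 0.0078), and Alk (-1.08 ± 0.13) were lower. Hoxb2 (2.24 ± 0.26, adjusted p = 0.0395), Hoxa2 (1.67 ± 0.19), Casp1 (1.43 ± 0.17) and Col26a1 (1.19 ± 0.13) were higher in IV ventricle NSC. These 7 genes were chosen after their values were seen.

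Cholesterol synthesis genes were higher as a list in IV ventricle than in cerebellar NSC (adjusted p = 1.61e-07; adjusted p = 0.573 with an estimated correlation), with 0 of 16 members called and small differences such as that of Msmo1 (0.24 ± 0.10). Hypoxia and glycolysis genes were lower as a list, with 0 of 19 called (adjusted p = 0.00176; adjusted p = 0.706 with an estimated correlation). That call was lost without cerebellar replicate 1 (adjusted p = 0.946), without IV ventricle replicate 2 (adjusted p = 0.186) and with the date mark as a block (adjusted p = 0.203). Both lists had 0 members called adjusted over the list alone. The Hox list did not pass (adjusted p = 0.0927; adjusted p = 0.706 with an estimated correlation), but passed without IV ventricle replicate 2 (adjusted p = 0.00136). With the date mark as a block 9 genes were called, among them Otx2 and En2. That fit gives IV ventricle replicate 2, alone in its mark, no weight. Within the shared mark 2 genes were called, with only 1 IV ventricle against 2 cerebellar arrays.

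The p53 wild-type tumour lines were compared with hindbrain NSC (the mean of IV ventricle and cerebellar NSC) to ask how tumour stem-like cells depart from normal stem cells of the same brain region. Aldh1l1, a folate enzyme used as an astrocyte marker, fell from 9.48 ± 0.52 (SD, n = 6) in hindbrain NSC to 2.75 ± 0.64 (SD, n = 8) in the lines, a difference of -6.73 ± 0.27 (adjusted p = 1.54e-10). The water channel Aqp4 fell by 2.06 ± 0.35 (adjusted p = 0.00157). Other astrocyte markers are not given for this comparison, so these genes do not speak for the astrocyte list as a whole. Lhx2, a LIM homeobox gene of the forebrain, rose by 2.82 ± 0.25 (adjusted p = 6.67e-06), although it remained below its level in SVZ NSC (-1.09, adjusted p = 0.049). Prm1, a protamine of sperm, rose by at least 3.13 (adjusted p = 1.37e-05) and St3gal6, a sialyltransferase, by 3.20 ± 0.44 (adjusted p = 3.76e-04). Of 18194 genes, 1740 were called, 638 higher and 1102 lower, of which 139 and 213 differed at least 2-fold.

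In the Shh pathway, Ptch1 itself was lower in the lines, at 6.63 ± 0.75 (SD, n = 8) against 8.26 ± 0.23 (SD, n = 6), a difference of -1.63 ± 0.32 (adjusted p = 0.00414). Where its probe set lies relative to the mutated allele is not known here, so it does not check the genotype. No probe set carried Trp53 as its only gene symbol, so that gene was not analysed here. Hhip, a hedgehog-binding protein whose gene is itself a pathway target, rose by 2.31 ± 0.38 (adjusted p = 0.00145) and Bmi1, a Polycomb gene, by 0.66 ± 0.13 (adjusted p = 0.0043). Of 22 measured Shh pathway genes 2 were higher and 1 lower (2 and 2 adjusted over the list alone), and the list as a whole was not called (adjusted p = 0.946). Of 27 Wnt pathway genes 2 were higher and 6 lower (2 and 7 adjusted over the list alone; adjusted p = 0.124). The ligand Wnt5a fell by 1.63 ± 0.19 (adjusted p = 9.03e-05) and Znrf3, a partner of Rnf43 in receptor removal, by 0.75 ± 0.12 (adjusted p = 0.00143). Lfng, a Notch glycosyltransferase, fell by 1.80 ± 0.21 (adjusted p = 9.03e-05).

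Several p53 target genes were lower in the lines than in hindbrain NSC. The labels give p53 as wild-type for these tumours, but the p53 state of the cultures was not checked here. The pro-apoptotic genes Pmaip1 (-1.77 ± 0.33, adjusted p = 0.00339) and Bbc3 (-0.85 ± 0.21, adjusted p = 0.0181) and the cell cycle inhibitor Cdkn1a (-0.95 ± 0.24, adjusted p = 0.0171; adjusted p = 0.0511 without IV ventricle replicate 2) fell. Of 30 p53 targets 1 was higher and 5 lower (1 and 6 adjusted over the list alone), and camera did not call the list (adjusted p = 0.0628). Of 4 Ebf factors, transcription factors of neuronal and B cell differentiation, 1 was higher (3 adjusted over the list alone; adjusted p = 0.0782), namely Ebf2 (0.78 ± 0.13, adjusted p = 0.00139). Of 21 oligodendrocyte lineage markers 5 were higher and 0 lower (6 and 2 adjusted over the list alone; adjusted p = 0.298). Among them was Ugt8a, which makes a myelin lipid (2.20 ± 0.36, adjusted p = 0.0014). Of 22 interferon response genes 2 were higher, Ifi27 (1.93 ± 0.35, adjusted p = 0.00276) and Ifit2 (1.27 ± 0.19, adjusted p = 7.19e-04), also 2 adjusted over the list alone. The interferon list was higher (adjusted p = 0.0162; adjusted p = 0.984 with an estimated correlation), a call lost without line 77 (adjusted p = 0.161). Ribosomal protein genes were lower as a list (adjusted p = 0.0162; adjusted p = 0.738 with an estimated correlation), with 4 of 20 lower (5 adjusted over the list alone), such as Rpl37 (-0.56 ± 0.08, adjusted p = 7.60e-04). That call was lost after cyclic loess (adjusted p = 0.12) and after quantile scaling (adjusted p = 0.152).

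No date mark held arrays of more than 1 of NSC, p53 wild-type lines and p53 heterozygous cultures. In the 3 comparisons between these groups, a difference between marks therefore cannot be told apart from a difference between groups. With the mark as a random block on all arrays 359 genes were called, and the calls of Ptch1 (-1.66, adjusted p = 0.0838), Bmi1 (0.64, adjusted p = 0.0762), Cdkn1a (-0.96, adjusted p = 0.167) and Bbc3 (-0.85, adjusted p = 0.167) were lost. That fit counts the 6 technical replicate arrays of the 2 p53 heterozygous tumours as separate samples. With 1 array per tumour 608 genes were called. Ptch1 (-1.65, adjusted p = 0.0364) and Bmi1 (0.65, adjusted p = 0.0385) kept their calls there, and Cdkn1a (-0.96, adjusted p = 0.0968) and Bbc3 (-0.85, adjusted p = 0.114) did not. All 4 differences lay close to those without the block, so the lost calls neither show nor exclude a part of the date in them. The 4 lines of the earlier mark gave 2150 called genes. There the interferon list (adjusted p = 0.321) and the ribosomal list (adjusted p = 0.0537) lost their calls. The 4 lines of the later mark gave 1003 called genes, with Bmi1 (0.50, adjusted p = 0.0838), Cdkn1a (-0.77, adjusted p = 0.164), Pmaip1 (-1.49, adjusted p = 0.0546) and Bbc3 (-0.86, adjusted p = 0.0607) no longer called. Leaving out IV ventricle replicate 2 lowered the count to 1060.

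To ask which NSC population the lines resembled most, the Euclidean distance over all 18194 genes was taken from each line to each NSC mean. All 8 p53 wild-type lines lay nearest to IV ventricle NSC. The distance to IV ventricle less that to SVZ NSC was -7.06 ± 2.52 (SD, n = 8; exact two-sided sign-flip p = 0.00781, adjusted p = 0.00781). That to cerebellar less SVZ NSC was -5.76 ± 2.91 (SD, n = 8; exact p = 0.00781, adjusted p = 0.00781). The distance to IV ventricle less that to cerebellar NSC was -1.30 ± 0.94 (SD, n = 8; exact p = 0.00781, adjusted p = 0.00781). Each of these 3 p-values is the smallest that 8 lines allow. The test takes the NSC means, which all lines share, as fixed. Its p-values therefore measure the spread between lines and not that between the 3 cultures behind each mean. With IV ventricle replicate 2 left out of its mean the last difference was -1.40 with 5 of 8 lines nearer to IV ventricle NSC (exact p = 0.102), so that ranking did not hold in all lines without that culture. Line 68 lay closest to IV ventricle NSC at 49.6, against 65.4 to 74.5 for the other lines. The p53 heterozygous tumours 27 and B lay at 119.7 and 119.1 from IV ventricle and at 119.7 and 119.0 from cerebellar NSC.

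The p53 heterozygous tumour cultures departed much further from hindbrain NSC. Hapln1, which links hyaluronan to proteoglycans in cartilage and brain matrix, was 9.24 ± 0.33 (SD, n = 2) against 0.94 ± 0.11 (SD, n = 6), a difference of at least 7.67 (adjusted p = 3.22e-14). Col9a1, a cartilage collagen, rose by 7.90 ± 0.50 (adjusted p = 3.16e-09) and the neuregulin receptor gene Erbb3 by 6.93 ± 0.33 (adjusted p = 9.87e-11). Gpm6a, a neuronal membrane glycoprotein, fell by 7.39 ± 0.30 (adjusted p = 1.71e-11), Thy1 by 6.61 ± 0.93 (adjusted p = 4.02e-05) and the growth factor receptor gene Egfr by 5.81 ± 0.48 (adjusted p = 1.02e-07). Of 18194 genes, 4878 were called, 2508 higher and 2370 lower, of which 1026 and 954 differed at least 2-fold. The group held only 2 tumours, whose spread was taken to be like that of the other cultures. With the date mark as a random block and 1 array per tumour 4697 genes were called, but the mark goes with the group here. Both tumour cultures lacked the Y-linked signal that all 6 hindbrain NSC carried, so sex, as read from the Y-linked genes, also goes with the group in this comparison.

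Against hindbrain NSC, 18 of 30 p53 targets were lower and 1 higher in the p53 heterozygous cultures (18 and 3 adjusted over the list alone). The list was lower (adjusted p = 1.43e-06; adjusted p = 0.407 with an estimated correlation). Eda2r, a death receptor gene, fell by 5.11 ± 0.47 (adjusted p = 4.01e-07), the epoxide hydrolase gene Ephx1 by 4.02 ± 0.24 (adjusted p = 1.84e-09), Cdkn1a by 2.78 ± 0.36 (adjusted p = 1.68e-05) and the nuclease gene Aen by 2.03 ± 0.27 (adjusted p = 2.42e-05). Rrm2b, a ribonucleotide reductase subunit, was higher (0.80 ± 0.18, adjusted p = 0.00284). Of 21 oligodendrocyte lineage markers 11 were higher and 3 lower (12 and 3 adjusted over the list alone). This list alone of the 7 called here passed with an estimated correlation (adjusted p = 9.89e-04; adjusted p = 0.0369 with an estimated correlation). Its call was lost with dim genes left out (adjusted p = 0.133). Sox10, a transcription factor of oligodendrocytes and neural crest, rose by 5.69 ± 0.38 (adjusted p = 5.93e-09), Ugt8a by 5.57 ± 0.55 (adjusted p = 8.92e-07) and the tight junction gene Cldn11 by at least 4.90 (adjusted p = 1.21e-08). Olig2 (-1.83 ± 0.17, adjusted p = 5.48e-07) and Nkx2-2 (-1.46 ± 0.18, adjusted p = 8.12e-06), which specify oligodendrocyte precursors, were lower.

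Neural stem and radial glial markers had 2 of 22 members higher and 11 lower (3 and 12 adjusted over the list alone; adjusted p = 3.35e-04, and adjusted p = 0.407 with an estimated correlation). Tnc differed by -5.61 ± 0.59, Nes by -2.42 ± 0.26 and Fabp7 by -1.91 ± 0.18. Neuron markers had 1 of 24 higher and 11 lower (1 and 12 adjusted over the list alone; adjusted p = 9.89e-04, and adjusted p = 0.407 with an estimated correlation). Pericyte and fibroblast markers had 7 of 18 higher and 0 lower (7 and 0 adjusted over the list alone; adjusted p = 0.0053, and adjusted p = 0.407 with an estimated correlation). Col6a1 was higher by 5.34 ± 0.52 and Col3a1 by at least 4.23 in the mean of 2 unlike tumours (1.78 without tumour B and 6.86 without tumour 27). Of 31 G2 and M phase genes 0 were higher and 13 lower (0 and 17 adjusted over the list alone), among them Cenpf (-1.37 ± 0.15) and the proliferation marker gene Mki67 (-0.99 ± 0.13). The list was lower (adjusted p = 1.74e-05; adjusted p = 0.805 with an estimated correlation). Cholesterol synthesis genes had 0 of 16 higher and 7 lower (0 and 10 adjusted over the list alone; adjusted p = 3.35e-04, and adjusted p = 0.59 with an estimated correlation). Hmgcs1 differed by -1.54 ± 0.17. Without tumour 27 the G2 and M phase and cholesterol lists lost their calls (adjusted p = 0.163 for each).

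In the Wnt pathway 4 of 27 genes were higher and 7 lower than in hindbrain NSC (4 and 8 adjusted over the list alone; adjusted p = 0.788). The secreted inhibitor Wif1 was up by at least 4.38 (adjusted p = 1.19e-08), Lef1 was up by 1.59 ± 0.15, and the feedback genes Nkd1 (-2.63 ± 0.26) and Axin2 (-1.75 ± 0.25) were down. In the Shh pathway 2 of 22 were higher and 6 lower (2 and 6 adjusted over the list alone; adjusted p = 0.788). The cyclins Ccnd2 (-3.32 ± 0.41; -1.98 without tumour B and -4.66 without tumour 27, both called) and Ccnd1 (-1.49 ± 0.12) were lower. The list's median was 0.12 while its mean was -0.03 and camera's direction was down. Ptch1 was 6.67 ± 1.30 (SD, n = 2) against 8.26 ± 0.23 (SD, n = 6; difference -1.60 ± 0.48, adjusted p = 0.0197), a call that was lost without tumour 27 (-0.68, adjusted p = 0.495) and kept without tumour B (-2.52). Of 4 Ebf factors 2 were higher (3 adjusted over the list alone; adjusted p = 0.171), among them Ebf2 (0.96 ± 0.19, adjusted p = 0.00117).

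The 2 genotypes were then compared directly. Erbb3 (6.92 ± 0.31, adjusted p = 7.54e-11), Hapln1 (at least 7.67, adjusted p = 3.39e-14) and Acan, the main proteoglycan of cartilage (6.16 ± 0.22, adjusted p = 1.78e-12), were higher in the p53 heterozygous than in the p53 wild-type cultures. Gpm6a (-6.30 ± 0.29, adjusted p = 8.09e-11), the potassium channel gene Kcnc1 (-5.95 ± 0.31, adjusted p = 4.24e-10) and Egfr (-5.34 ± 0.46, adjusted p = 1.87e-07) were lower. Ptch1 was not called between them (0.03 ± 0.47, adjusted p = 0.974), but that value averages 2 tumours on opposite sides of the mean of the wild-type lines (-0.88 without tumour B and 0.95 without tumour 27, neither called). Of 18194 genes, 4782 were called, 2636 higher and 2146 lower, of which 988 and 822 differed at least 2-fold. The count was 4265 with the date mark as a random block and 1 array per p53 heterozygous tumour, 5177 against the 4 lines of the earlier mark and 4155 against those of the later mark.

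Against the p53 wild-type lines 12 of 30 p53 targets were lower and 2 higher (14 and 2 adjusted over the list alone; adjusted p = 3.50e-05, and adjusted p = 0.66 with an estimated correlation). Ephx1 fell by 3.78 ± 0.23, the kinase gene Plk2 by 2.50 ± 0.36 (3.21 without tumour B and 1.80 without tumour 27) and Trp53inp1 by 2.01 ± 0.30. Neural stem and radial glial markers had 2 of 22 higher and 12 lower (2 and 13 adjusted over the list alone; adjusted p = 3.50e-05, and adjusted p = 0.559 with an estimated correlation). Sox9 differed by -3.55 ± 0.36 and Fabp7 by -1.98 ± 0.17. Oligodendrocyte lineage markers had 10 of 21 higher and 3 lower (11 and 3 adjusted over the list alone; adjusted p = 0.00913, and adjusted p = 0.145 with an estimated correlation). Sox10 differed by 5.83 ± 0.36 and Gpr17 by 5.12 ± 0.55, while Olig2 differed by -1.50 ± 0.17. The list lost its call with dim genes left out (adjusted p = 0.393). Neuron markers (1 of 24 higher and 7 lower, also adjusted over the list alone; adjusted p = 0.00913, and adjusted p = 0.66 with an estimated correlation) were lower. Pericyte and fibroblast markers (6 of 18 higher and 0 lower, also adjusted over the list alone; adjusted p = 0.00913, and adjusted p = 0.66 with an estimated correlation) were higher. The latter list lost its call against the lines of the later mark (adjusted p = 0.0618).

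Genes of cell division were lower in the p53 heterozygous cultures. Of 31 G2 and M phase genes 11 were lower and 0 higher (also 11 and 0 adjusted over the list alone; adjusted p = 3.47e-05, and adjusted p = 0.895 with an estimated correlation). Cenpf differed by -1.47 ± 0.15 and Mki67 by -1.15 ± 0.13. Of 29 S phase genes 7 were lower and 0 higher (7 and 0 adjusted over the list alone; adjusted p = 0.0189, and adjusted p = 0.938 with an estimated correlation). Rrm2 differed by -1.90 ± 0.30 (-2.93 without tumour B and -0.86 without tumour 27, both called). Of 16 cholesterol synthesis genes 9 were lower and 1 higher (11 and 1 adjusted over the list alone; adjusted p = 1.24e-04, and adjusted p = 0.66 with an estimated correlation). These 3 lists lost their calls without tumour 27 and kept them without tumour B: without tumour 27 the adjusted p was 0.266 for G2 and M phase, 0.126 for cholesterol synthesis and 0.408, with the direction turned, for S phase. The S phase list also lost its call without line 83 (adjusted p = 0.0548), after cyclic loess (adjusted p = 0.0534), with dim genes left out (adjusted p = 0.213) and against the lines of the earlier mark (adjusted p = 0.14).

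Among single genes of the Wnt pathway, Wif1 (at least 4.38, adjusted p = 9.28e-09) was higher and the ligand gene Wnt5a (-2.05 ± 0.27, adjusted p = 2.35e-05) lower in the p53 heterozygous cultures. In all 5 of 27 genes of the pathway were higher and 5 lower (6 and 5 adjusted over the list alone; adjusted p = 0.959). Its median was 0.01 and its mean 0.07, while camera's direction was down. The imprinted genes Grb10 (5.78 ± 0.40, adjusted p = 1.16e-08) and Mest (-3.57 ± 0.60, adjusted p = 2.45e-04; -4.54 without tumour B and -2.61 without tumour 27) moved apart. So did Snai2 (3.81 ± 0.24, adjusted p = 2.69e-09) and Zeb1 (-2.84 ± 0.14, adjusted p = 2.15e-10), transcription factors of epithelial-mesenchymal transition. Genes called in the same direction against hindbrain NSC in both genotypes numbered 769, 244 higher and 525 lower, with 136 in opposite directions. Independent lists would share 88.0 higher and 144 lower (87.95 and 143.5), and unchanged groups simulated against the shared NSC shared 0 called genes over 50 draws. Unchanged groups yield hardly any calls, so that 0 does not show how far the shared NSC raise the overlap. With IV ventricle NSC as the control of the wild-type and cerebellar NSC as that of the heterozygous cultures 283 were shared, and 304 with these controls exchanged. The fold changes of the 2 genotypes correlated across genes at r = 0.382, against 0.375 in the simulation, with a covariance of 0.12 against 0.0161; genes are not independent replicates. The NSC genes of the hindbrain were also followed as a set. As 0 genes were called between IV ventricle and cerebellar NSC, the planned regional sets were empty, and the 55 genes higher in both hindbrain NSC than in SVZ NSC were used, a set chosen after the data were seen. They were lower in the p53 wild-type lines than in hindbrain NSC, with 3 higher and 11 lower (adjusted p = 4.74e-04; adjusted p = 0.0434 with an estimated correlation). In the p53 heterozygous cultures 7 were higher and 22 lower than in hindbrain NSC (adjusted p = 0.00132; adjusted p = 0.0626 with an estimated correlation), and between the genotypes the set was not called (adjusted p = 0.111). These genes were picked as high in the same hindbrain NSC, so regression towards the mean can add to their fall. The 61 genes of the reverse set were not called in these 3 comparisons (adjusted p = 0.332, 0.163 and 0.271).

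**Figure D3:**
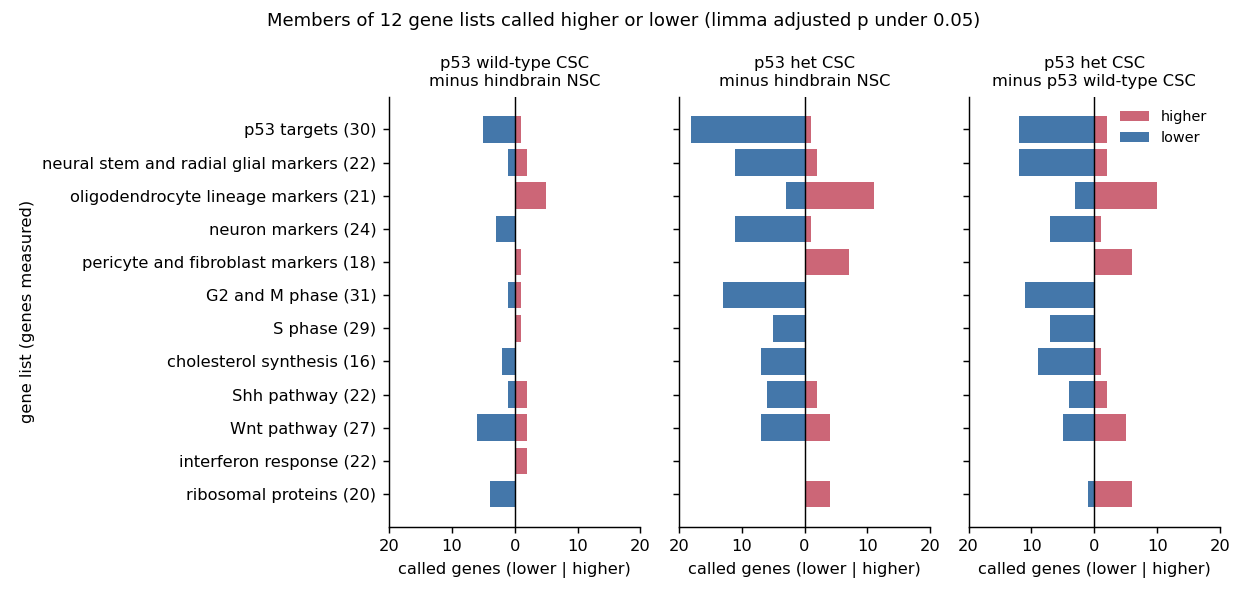
Numbers of genes called higher (right) or lower (left) in 12 gene lists for 3 comparisons of tumour cultures, with the number of measured genes in brackets. The p53 targets show 5 lower genes in p53 wild-type lines against hindbrain NSC, 18 lower in the p53 heterozygous cultures against hindbrain NSC and 12 lower between the genotypes.

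Whole chromosomes also differed in median expression in the tumour cultures. A chromosome-wide shift, the median log2 difference from hindbrain NSC over the brighter genes of a chromosome, reached at least 0.2 in size 21 times, in 10 of 10 tumour cultures and in 0 of 9 NSC cultures, where the highest was 0.06. Chromosome 6 was shifted by 0.51, 0.54 and 0.44 in lines 91, 92 and 9, chromosome 11 by 0.44 and 0.41 in lines 74 and 77, and chromosome 1 by 0.57 in line 49. Chromosome 15 was shifted by 0.58 in tumour 27 and by 0.59 in tumour B, and tumour 27 had lower chromosomes 12 (-0.70) and 18 (-0.67). For comparison, 3 copies in place of 2 would give 0.58 with expression proportional to copy number. On the 7 chromosomes without a shift in either p53 heterozygous tumour, 23.6% of 6671 genes were called between the genotypes, against 31.1% of 5953 genes on the 8 shifted chromosomes. The 7 include chromosomes 6 and 11, which were shifted in wild-type lines. On the 5 chromosomes without a shift in any tumour culture (2, 10, 13, 14 and 16) 25.7% of 4222 genes were called, 24.3% to 27.7% per chromosome. Tested on the 7 chromosomes alone, the p53 target list lost its call against hindbrain NSC (adjusted p = 0.266) and against the wild-type lines (adjusted p = 0.362). G2 and M phase (adjusted p = 0.0602 and 0.0717) lost it too, as did the neural stem list against hindbrain NSC (adjusted p = 0.0602) and the neuron list against the wild-type lines (adjusted p = 0.0596). The oligodendrocyte list turned direction in camera there without a call (adjusted p = 0.705 and 0.737). Fewer members lie there: 11 of 30 p53 targets, 14 of 31 G2 and M phase genes, 11 of 22 neural stem, 7 of 21 oligodendrocyte and 10 of 24 neuron markers. Against hindbrain NSC the median of the p53 targets was -0.23 there and -1.46 on the other chromosomes, and against the wild-type lines -0.04 and -1.20. For G2 and M phase the medians were -0.33 and -0.65 against hindbrain NSC, and -0.35 and -0.45 against the lines. The neural stem markers had medians of -0.44 and -1.33 against hindbrain NSC. The neuron markers had medians of -0.95 and -0.29 against the lines, so their lost call goes with fewer members and not with a smaller change. The oligodendrocyte markers kept positive medians there, 0.32 against hindbrain NSC and 0.57 against the lines. On the 5 chromosomes, between the genotypes, the neuron (adjusted p = 0.028), pericyte and fibroblast (adjusted p = 0.00463) and cholesterol (adjusted p = 0.00463) lists were called. The p53 target (adjusted p = 0.291), S phase (adjusted p = 0.179), G2 and M phase (adjusted p = 0.388) and neural stem (adjusted p = 0.377) lists were not. The oligodendrocyte list, with 5 members there, turned direction without a call (median -0.92, adjusted p = 0.271).

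**Figure D4:**
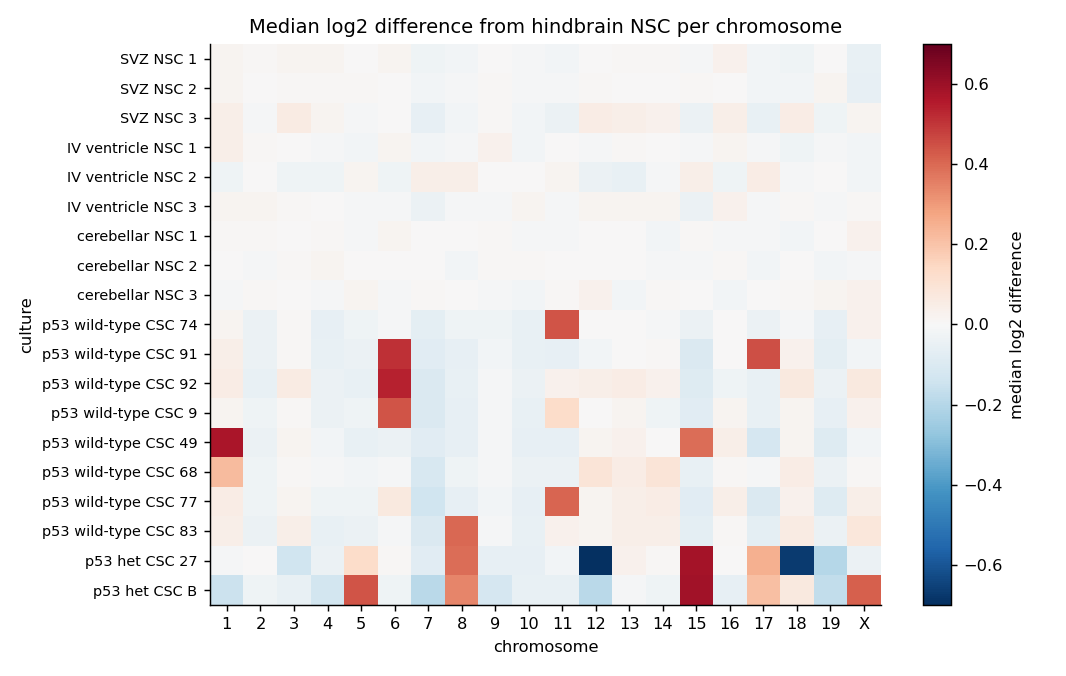
Median log2 difference from hindbrain NSC for each chromosome (columns) in each NSC and tumour culture (lines of the map); red is higher and blue lower. The 9 NSC cultures stay within 0.06, while single chromosomes reach 0.57 in p53 wild-type line 49 and -0.70 in p53 heterozygous tumour 27.

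Set against the tumours they came from, the 8 p53 wild-type lines read low for genes of the granule neuron lineage. Whether cells lost these genes in culture or the lines grew from cells without them was not tested. Neurod1, a transcription factor of differentiating granule neurons, fell from 10.2 ± 0.16 (SD, n = 8) in tissue to 1.83 ± 1.02 (SD, n = 8) in the lines, a paired difference of -8.38 ± 0.30 (adjusted p = 1.27e-08). Atoh1, which specifies granule neuron precursors, fell by 5.45 ± 0.14 (adjusted p = 1.56e-09), Mycn, a hedgehog-driven Myc family gene, by 6.88 ± 0.17 (adjusted p = 8.91e-10), and Nhlh2 by at least 7.35 (adjusted p = 3.74e-12). All 23 measured granule neuron lineage genes were lower (23 also adjusted over the list alone). This list alone of the 10 called here passed with an estimated correlation (adjusted p = 3.15e-16; adjusted p = 0.00115 with an estimated correlation). The stem cell genes Sox3 (5.10 ± 0.19, adjusted p = 1.76e-08), Sox2 (4.32 ± 0.16, adjusted p = 1.51e-08), Nes (2.95 ± 0.11, adjusted p = 1.14e-08) and the receptor gene Notch1 (4.23 ± 0.11, adjusted p = 1.56e-09) were higher in the lines. Of 18194 genes, 9033 (49.7%) were called, 4831 higher and 4202 lower in the lines, of which 1305 and 1457 differed at least 2-fold. The split depended on scaling: 53.5% of called genes were higher here, 48.4% after cyclic loess and 66% after shifting each array to the same median.

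Markers of cell types that a tumour also holds were mostly lower in the lines. Of 21 microglia and macrophage markers 20 were lower and 1 higher (20 and 1 adjusted over the list alone; adjusted p = 3.15e-16, and adjusted p = 0.201 with an estimated correlation). The complement gene C1qb was lower by 7.09 ± 0.12 and the cathepsin gene Ctss by at least 7.40. The exception, Laptm5 (0.32 ± 0.09, adjusted p = 0.0172), was lower when its probe sets were averaged (-1.29). Of 17 endothelial markers 16 were lower and 1 higher (16 and 1 adjusted over the list alone; adjusted p = 6.50e-08, and adjusted p = 0.105 with an estimated correlation). Cldn5 differed by -3.38 ± 0.13. Of 18 pericyte and fibroblast markers 15 were lower and 2 higher (15 and 2 adjusted over the list alone; adjusted p = 3.42e-05, and adjusted p = 0.377 with an estimated correlation). With dim genes left out that call was lost and the direction turned (adjusted p = 0.727). Rgs5 differed by -5.62 ± 0.13. Of 24 neuron markers 21 were lower and 0 higher (21 and 0 adjusted over the list alone; adjusted p = 1.13e-11, and adjusted p = 0.161 with an estimated correlation). Stmn2 was lower by 7.74 ± 0.13 and the glutamate transporter gene Slc17a6 by at least 7.02. Astrocyte markers had 3 of 18 higher and 10 lower (3 and 10 adjusted over the list alone; adjusted p = 0.122). Aqp4 differed by -5.97 ± 0.34 and Gfap by -3.64 ± 0.39. Oligodendrocyte lineage markers divided into 6 higher and 8 lower of 21 (6 and 8 adjusted over the list alone; adjusted p = 0.712). Olig2 differed by 3.85 ± 0.13 and Pdgfra by -3.20 ± 0.34. The list median was -0.18 and the mean 0.15.

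All 16 measured cholesterol synthesis genes were higher in the lines (16 also adjusted over the list alone; adjusted p = 3.20e-12, and adjusted p = 0.201 with an estimated correlation). Cyp51 differed by 3.13 ± 0.09, Hmgcs1 by 2.88 ± 0.08 and Sqle by 2.73 ± 0.08. Neural stem and radial glial markers had 14 of 22 higher and 5 lower (14 and 5 adjusted over the list alone; adjusted p = 0.00733, and adjusted p = 0.591 with an estimated correlation), with Pax6 (-2.87 ± 0.10) and Msi1 (-1.28 ± 0.11) among those lower. Of 31 G2 and M phase genes 20 were higher and 0 lower (20 and 0 adjusted over the list alone; adjusted p = 0.00544, and adjusted p = 0.737 with an estimated correlation). Plk1 differed by 1.02 ± 0.12. With the date mark in place of the tumour as a block the adjusted p was 0.122. Hypoxia and glycolysis genes had 11 of 19 higher and 2 lower (11 and 2 adjusted over the list alone; adjusted p = 0.0248, and adjusted p = 0.737 with an estimated correlation). Adm differed by 3.75 ± 0.22 and Hk2 by -2.64 ± 0.39. The call was lost without line 92 (adjusted p = 0.0719) and after median scaling (adjusted p = 0.0709). Ribosomal protein genes had 1 of 20 higher and 13 lower (1 and 13 adjusted over the list alone; adjusted p = 0.00248, and adjusted p = 0.659 with an estimated correlation). Rps14 differed by -0.53 ± 0.05.

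Of 22 Shh pathway genes 8 were higher and 9 lower in the lines than in tissue (8 and 10 adjusted over the list alone; adjusted p = 0.161). Beside Mycn, the co-receptor gene Boc (-2.60 ± 0.10, adjusted p = 1.44e-08) and Ptch1 (-1.63 ± 0.29, adjusted p = 9.82e-04; 6.63 ± 0.75 against 8.26 ± 0.42, SD, n = 8) were lower. Ccnd1 (1.57 ± 0.08, adjusted p = 2.04e-07) and the hedgehog scaffold gene Kif7 (1.12 ± 0.07, adjusted p = 4.39e-07) were higher. Of the 5 genes of the human SHH medulloblastoma panel 1 was higher and 2 lower (1 and 3 adjusted over the list alone; adjusted p = 0.102). The lower ones were Atoh1 and the Wnt antagonist gene Sfrp1 (-7.03 ± 0.41, adjusted p = 3.29e-07). Of 4 Ebf factors 1 was higher and 3 lower (1 and 3 adjusted over the list alone; adjusted p = 0.106). Ebf3 differed by -4.10 ± 0.33 (adjusted p = 3.90e-06) and Ebf1 by -3.83 ± 0.33 (adjusted p = 5.62e-06). Of 30 p53 targets 16 were higher and 8 lower (16 and 8 adjusted over the list alone; adjusted p = 0.179). The 4 pairs in which line and tissue share a date mark gave 7307 called genes. The other 4 pairs gave 5935, but there each tissue carries another mark than its line, so mark and group cannot be told apart. The date mark in place of the tumour as a block gave 7356, which rests on the 4 pairs with a shared mark.

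**Figure D5:**
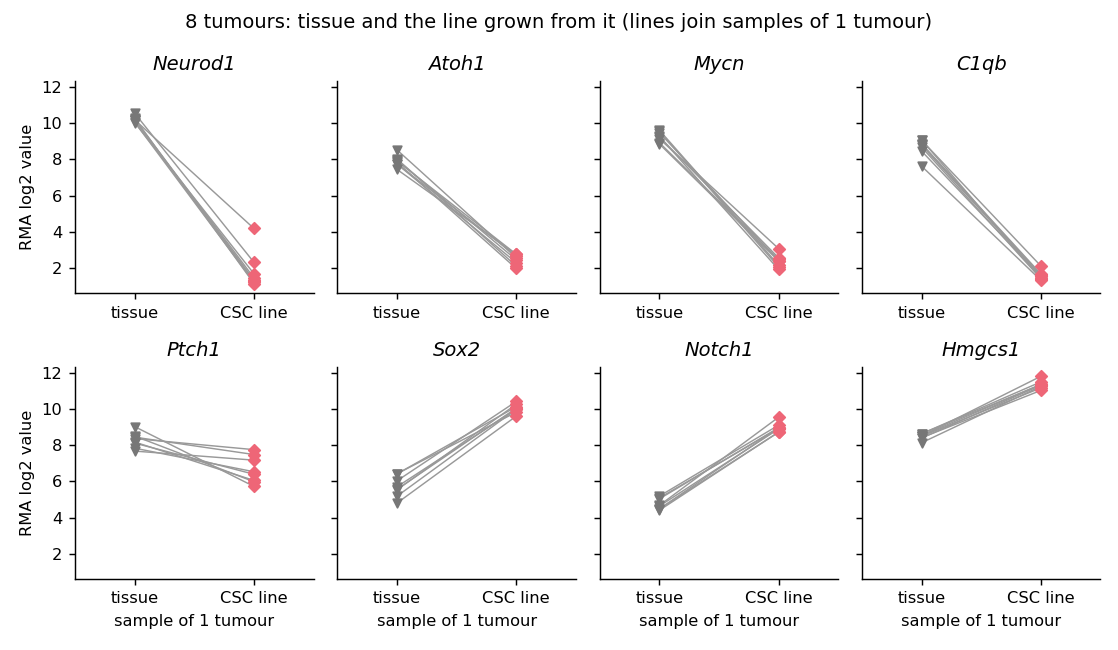
RMA log2 values of 8 genes in 8 tumour tissues (triangles) and the 8 p53 wild-type CSC lines grown from them (diamonds); each thin line joins the samples of 1 tumour. Neurod1, Atoh1, Mycn and C1qb are lower in all 8 lines, and Sox2, Notch1 and Hmgcs1 are higher in all 8.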

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

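Of the tests below, those of a swapped label and of cerebellar tissue in IV ventricle replicate 2, and those of chromosome shifts as the whole cause of the genotype calls, were chosen after the result was seen. Samples far from the rest of their group were sought with Dixon's test in the groups of 8. Of 223 tests 30 passed, where chance gives 11.2, so single genes carry little weight. Each value below is the gap to the nearest other sample divided by the range of the group.

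Line 68 stood apart from the other p53 wild-type lines in several genes that were high in the p53 heterozygous cultures. It was highest for Gpr17 (5.31 against 3.41 in the next line, 0.727), Cldn11 (2.13 against 1.61, 0.67), Erbb3 (3.43 against 2.39, 0.653), Cthrc1 (2.72 against 1.86, 0.652) and Sox10 (5.48 against 4.44, 0.595). It was also highest for Sel1l3 (4.70 against 3.34, 0.654) and Ina (4.03 against 2.82, 0.61) and lowest for S100b (5.44 against 6.88, 0.537). The lowest lines read 1.35 for Cldn11 and 1.40 for Cthrc1, at the level of genes that are not expressed. Line 49 was highest for Col6a1 (4.38 against 2.97, 0.767), Tubb3 (5.69 against 3.81, 0.625), Neurod1 (4.19 against 2.32, 0.614), C1qb (2.12 against 1.68, 0.548), Notch1 (9.54 against 9.10, 0.533) and Dll1 (7.14 against 6.26, 0.531), and lowest for Olig2 (9.37, 0.715). Line 77 was highest for Otx2 (4.20 against 1.86, 0.783), the interferon genes Ifit2 (7.37 against 6.63, 0.643) and Ifi27 (10.27 against 8.54, 0.62), and Znrf3 (5.91 against 5.44, 0.537). Line 83 was highest for Wif1 (2.70 against 1.48, 0.728) and lowest for Kif7 (5.50 against 5.73, 0.592) and the p53 targets Eda2r (next line 5.92, 0.579) and Trp53inp1 (7.84 against 8.78, 0.562). Line 92 was highest for the glycolysis genes Pgk1 (11.89 against 11.24, 0.595) and Hk2 (8.77 against 6.23, 0.591), and line 91 for Hapln1 (1.95 against 1.28, 0.708). Among the tissues, that of tumour 91 was lowest for C1qa (7.72 against 8.69, 0.639) and C1qb (7.63 against 8.46, 0.57), that of 68 highest for Irx3 (4.52 against 3.50, 0.626) and that of 9 lowest for Mcm7 (10.50 against 10.77, 0.545).

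The change from hindbrain NSC differed between the genotypes for 8 lists, tested as the direct contrast. They were p53 targets (adjusted p = 3.50e-05), neural stem and radial glial markers (3.50e-05), G2 and M phase (3.47e-05), cholesterol synthesis (1.24e-04), S phase (0.0189), oligodendrocyte lineage (0.00913), neuron (0.00913) and pericyte and fibroblast markers (0.00913). With an estimated correlation, in the same order, the adjusted p was 0.66, 0.559, 0.895, 0.66, 0.938, 0.145, 0.66 and 0.66.

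IV ventricle replicate 2 correlated more closely with the cerebellar NSC than with the other IV ventricle NSC (mean r = 0.9857 with its own group and 0.9916 with the cerebellar cultures, a margin of -0.00591). Its positional score, the mean of En1 and En2 less that of Hoxa2, Hoxa3, Hoxa4, Hoxb2 and Hoxb3, was 4.05, against 2.85 to 3.92 in cerebellar and -1.40 and -0.38 in the other IV ventricle cultures. A swap with a cerebellar culture is argued against, since the lowest score of a cerebellar culture was 2.85, although by correlation 2 of 3 cerebellar cultures lay slightly nearer to IV ventricle replicates 1 and 3 (margins of -0.0012 and -9.96e-04), which a swap also predicts. RNA degradation is argued against by a Gapdh 3' to 5' difference of 0.275, within the 0.0586 to 0.644 of the other NSC. Cerebellar tissue in that sample or a single wrong label may explain it, and these cannot be separated here; a date mark carried by this NSC array alone was not tested.

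Chromosome-wide shifts occurred in all 10 tumour cultures. A median of 81.7% of the genes of a shifted chromosome lay on the side of the shift. A shift is itself a median, so most genes lie there by definition. This share is therefore no separate test of a few strongly changed genes. Array brightness is argued against, since 21 of 21 shifts stayed at 0.1 or more in both the dimmer and the brighter of the 9082 genes used. A local gene cluster is argued against, since 21 of 21 stayed so in both parts of the chromosome. A candidate explanation is gain or loss of chromosomes, which no DNA measurement tested here.

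The calls between the genotypes could come in part from these shifts. As the whole cause, through the genes of the shifted chromosomes themselves, they are argued against. On the 5 chromosomes without a shift in any of the 10 cultures 25.7% of genes were called (24.3% to 27.7% per chromosome). On the 7 chromosomes without a shift in the 2 p53 heterozygous tumours it was 23.6% (18.6% to 27.7%), but 2 of these 7 were shifted in wild-type lines. Effects of the shifted chromosomes on genes elsewhere were not tested. As a part of the cause they stay open, since the share on the 7 chromosomes was 0.759 of that on the chromosomes shifted in these tumours (0.739 to 0.787 with 1 chromosome left out). The date of the arrays stays open too. Called genes differed between technical replicates of 1 tumour under different date marks by a median of at most 0.225, against 0.817 between the genotypes, but the genotypes shared no date mark. The p53 genotype, the biological difference the design names, also stays open. It was not tested apart from the date marks or from the identity of the 2 tumours.

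Other splits of the samples into groups of the same sizes were compared by their called genes. For p53 wild-type lines against hindbrain NSC 1 of 100 splits, the real one, gave 1740, and the highest other gave 232. That is the smallest share that 100 splits allow, which argues against chance but does not exclude it. A difference between date marks, which these groups do not share, stays open. For lines against tissue 1 of 100 gave 9033 and the highest other 9, which argues against chance to the same degree. For IV ventricle against SVZ NSC 1 of 10 gave 139 and the highest other 0, and for cerebellar against SVZ NSC 1 of 10 gave 201 and the highest other 0; 10 splits are too few for a share under 0.05. For IV ventricle against cerebellar NSC 10 of 10 gave at least the real 0. The split with cerebellar 1 and 3 and IV ventricle 2 on the same side gave 76 and another gave 39, which points to a structure of these 6 samples other than the region in their labels.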

How the results depend on the processing

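Among the alternatives, the date marks of NSC and tissue arrays, the random block with 1 array per tumour, the chromosomes without a shift and the IV ventricle mean of 2 arrays were chosen after the data were seen. The genes followed by name are only some of those the rule names, and the shares below hold for these alone. Called genes stayed called in every setting for 7 of 19 in IV ventricle NSC vs SVZ NSC and 7 of 13 in cerebellar NSC vs SVZ NSC. The shares were 22 of 47 in p53 wild-type CSC vs hindbrain NSC and 47 of 53 in p53 het CSC vs hindbrain NSC. They were 42 of 50 in p53 het CSC vs p53 wild-type CSC and 67 of 73 in p53 wild-type CSC vs matched tumour tissue. Of all called lists, 1 stayed called in every setting, the granule neuron lineage against tissue. Unless a reason is given, the cause was not tested.

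With an estimated correlation, gene lists called numbered 0 for IV ventricle NSC vs cerebellar NSC, 0 for IV ventricle NSC vs SVZ NSC, 0 for cerebellar NSC vs SVZ NSC, 0 for p53 wild-type CSC vs hindbrain NSC, 1 for p53 het CSC vs hindbrain NSC, 0 for p53 het CSC vs p53 wild-type CSC and 1 for p53 wild-type CSC vs matched tumour tissue. With dim genes left out they numbered 4 for IV ventricle NSC vs cerebellar NSC, 3 for IV ventricle NSC vs SVZ NSC, 0 for p53 wild-type CSC vs hindbrain NSC and 5 for p53 het CSC vs p53 wild-type CSC, where fewer genes are tested, and genes called numbered 91 for IV ventricle NSC vs SVZ NSC and 123 for cerebellar NSC vs SVZ NSC.

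IV ventricle NSC vs cerebellar NSC gave 9 called genes with the date mark as a block and 2 in the arrays of mark m7 alone, which hold 1 IV ventricle array. IV ventricle NSC vs SVZ NSC gave 82 in a fit of all 27 units and 58 in mark m7. The comparison cerebellar NSC vs SVZ NSC gave 120 at a 2-fold minimum, 349 with only the arrays compared, 121 in a fit of all 27 units and 728 with the date mark as a block.

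For p53 wild-type CSC vs hindbrain NSC, every probe set gave 3084 (more features tested), a 2-fold minimum 352, the date mark as a random block 359 (the 6 technical replicate arrays counted as separate samples) or 608 (1 array per p53 heterozygous tumour), the reference IV ventricle alone 593, and cerebellum alone 673 (fewer arrays), the reference SVZ alone 1064 (fewer arrays and another region), and the 4 lines of mark m10 1003. With the SVZ reference the forebrain list (adjusted p = 0.0309), the midbrain-hindbrain list (adjusted p = 0.00114), Lhx2 (-1.09) and Irx3 (1.85) changed direction, since SVZ cells have another regional code. For p53 het CSC vs hindbrain NSC, every probe set gave 9918, a 2-fold minimum 1980 and the chromosomes without a shift 1559. For p53 het CSC vs p53 wild-type CSC these were 9673, 1810 and 1522, and 1093 on chromosomes without a shift in any tumour culture. For p53 wild-type CSC vs matched tumour tissue every probe set gave 20041, a 2-fold minimum 2762, the 4 pairs with lines of mark m10 and tissues of m11 or m12 5935 and the fit without the paired tumour block 8984. Genes called with a 2-fold change in the same direction in both genotypes numbered 182, with 14 in opposite directions.

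On chromosomes without a shift the oligodendrocyte list changed direction (adjusted p = 0.705 for p53 het CSC vs hindbrain NSC, 0.737 for p53 het CSC vs p53 wild-type CSC, and 0.271 for the latter on chromosomes without a shift in any tumour culture). So did the list S phase, p53 het CSC vs p53 wild-type CSC, without tumour 27 (0.408, and 3.84e-11 without tumour B), the pericyte and fibroblast list against tissue with dim genes left out (0.727) and Laptm5 with the mean of its probe sets (-1.29).

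Leaving out each culture in turn gave 0 to 7 called genes for IV ventricle NSC vs cerebellar NSC (7 without IV ventricle replicate 2), 51 (SVZ 2) to 181 (IV ventricle 2) for IV ventricle NSC vs SVZ NSC and 61 (SVZ 1) to 245 (cerebellar 2) for cerebellar NSC vs SVZ NSC. It gave 1060 (IV ventricle 2) to 1896 (line 49) for p53 wild-type CSC vs hindbrain NSC, 3781 (tumour 27) to 4697 (IV ventricle 2) for p53 het CSC vs hindbrain NSC, 3588 (tumour 27) to 4980 (line 49) for p53 het CSC vs p53 wild-type CSC and 8277 (line 9) to 8663 (line 49) for p53 wild-type CSC vs matched tumour tissue. A lone tumour left in a group was assumed to vary like the other groups.

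The distance of the lines to IV ventricle less cerebellar NSC was -1.4 with the IV ventricle mean of 2 arrays (exact p = 0.102). It lay between -1.47 (without line 92) and -1.05 (without line 9), IV ventricle less SVZ between -7.75 (line 49) and -6.63 (line 68), and cerebellar less SVZ between -6.46 (line 49) and -5.2 (line 68). No background level is given per probe set, so differences with a group at the level of Y-linked genes in samples without a Y are given only as bounds. The exceptions are the differences of Col3a1 with a p53 heterozygous tumour left out, which are given as measured.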

Other observations

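The tests of the 4 added lists were chosen after the result was seen. The p53 heterozygous cultures had higher Sox10, Erbb3, Hapln1 and Acan and lower Olig2 than the p53 wild-type lines, and 4 cell states were written as lists and tested on members not looked at before. A state like neural crest and Schwann cells (adjusted p = 0.688; 2 of 13 higher, 1 lower) and one like oligodendrocyte precursors (adjusted p = 0.688; 3 of 13 higher, 3 lower) were not supported. Cartilage genes were higher (adjusted p = 6.91e-06; adjusted p = 0.0147 with an estimated correlation), with 8 of 18 higher and 0 lower and a median log2 difference of 0.69. They included Cnmd (6.99 against 1.44, a level near that of genes that are not expressed), Col2a1 (5.16), Col9a3 (4.76) and Col11a1 (4.04). Melanocyte genes were also higher (adjusted p = 0.0319; adjusted p = 0.304 with an estimated correlation), with 4 of 13 higher, among them Dct (2.36), Pmel (1.79) and Mitf (1.72). The cartilage gene Sox9, looked at before and so left out of the test, was lower (-3.55). These tests do not decide whether the 2 cultures hold a cartilage-like state, since the pattern was found in the same 2 tumours.

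Of the sex-linked genes, Eif2s3y went with the group in 1 comparison, while Xist overlapped between these groups. Both p53 heterozygous cultures had Xist at 9.1 and 8.5 and Eif2s3y at 1.1 and 1.0, while all 6 hindbrain NSC had Eif2s3y at 4.7 to 6.4. The wild-type lines and the SVZ cultures were divided. Among the wild-type lines only 92 and 68 carried Y-linked signal, so sex, as read from it, was also unbalanced between these lines and hindbrain NSC. NSC replicate 2 of all 3 regions had Xist at 3.1 to 3.6 and Eif2s3y at 6.3 to 6.4. Replicates 1 and 3 of the IV ventricle and cerebellar cultures, and SVZ replicate 3, had both Xist (6.9 to 9.3) and Eif2s3y (4.7 to 6.1). SVZ replicate 1 had Xist at 9.7 and Eif2s3y at 1.3. Lines 92 and 68 and their tissues had Eif2s3y at 5.6 to 6.9, and the other 6 lines and tissues at 0.7 to 1.2. Line 91 had Xist at 3.3 and its tissue at 5.7, with Eif2s3y at 0.9 in both.

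The chromosome profile of a line matched that of its own tissue best in 2 of 8 tumours (mean r = 0.169, one-sided permutation p = 0.145). Chromosome 17 of tumour 91 was shifted by 0.45 in the line and by 0.41 in the tissue. The other shifts of wild-type lines outside chromosome 6 were not seen in their tissues. Chromosome 11 read 0.44 and 0.41 in lines 74 and 77, and 0.03 and 0.01 in their tissues. Chromosome 1 read 0.57 and 0.22 in lines 49 and 68, and -0.02 and -0.03 in the tissues. Chromosome 15 of line 49 (0.39) read 0.02 in the tissue, and chromosome 8 of line 83 (0.40) read 0.00. Whether these shifts arose in culture was not tested. Chromosome 6 was shifted by 0.51, 0.54 and 0.44 in lines 91, 92 and 9 and by 0.23, 0.26 and -0.17 in their tissues, measured against the median of the other tissues. The tissues of 74, 49 and 68, whose lines had no such shift, read -0.30, -0.25 and 0.15 on it. The tissues that serve as the reference were thus themselves divided on this chromosome.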
